A study of Homo sapiens with 12 samples.

How the data were processed

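RNA of 12 samples was measured, 3 in each of 4 groups made by the lines U87 and U373 and the treatments PBS and 1 U/ml BCT-100 for 72 h. Groups were taken from the treatment label of each sample, because the protocol label states the PBS control for every sample. According to the submitters' notes, reads were aligned to hg38 with STAR and quantified with RSEM, without versions. The authors deposited one signal value per gene and library, which the values show to be RSEM expected counts divided by one scaling factor per library. Of the values, 85.5% to 86.9% were whole within 0.001 after that division was undone, and all had at most 2 decimals within 2e-04. The recovered depths ran from 18.89 to 25.92 M reads, and intervals and floors take no account of anything but counting error.

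The table held 19844 entries. Of these, 20 repeated another entry of the same symbol and were dropped, 42 of those kept share a symbol, and 2478 were at 0 in every library. Symbols were matched to GENCODE v29 on GRCh38 for positions, GC content and transcript length, and 18646 matched while 1178 did not.

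The design written before the data were examined assumed counts, with TMM normalisation, a low-count filter and a quasi-likelihood test of a count model. The deposited values are scaled, so this was departed from. The main test was limma with a trended and robust prior on log2 of the value plus 1, keeping the authors' scaling, with genes at a value of at least 10 in at least 3 libraries (R 4.3.3, limma 3.58.1). All 12 samples were fitted with 4 group means, which leaves 8 residual degrees of freedom, and p-values were adjusted by Benjamini and Hochberg at 0.05. The contrasts were BCT-100 against PBS in each line, the difference of these responses (U87 minus U373), and U87 against U373 in PBS. The threshold test against a fold of 1.5 was limma's treat. A gene near 0 in a single line takes part of its shared spread from the other line, which limits the test for such genes.

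The groups, the contrasts, 31 lists with 760 memberships in all, a panel of 20 genes and the rule for named genes were fixed before the data were examined. Lists overlap, since genes such as BIRC3, SOD2 and TNFRSF10B belong to more than a single list. The lists cover the integrated stress response, amino acid synthesis, transporters, tRNA synthetases, arginine, polyamines, autophagy, DNA replication, mitosis, histones, p53, BCL2, ER chaperones, cholesterol, fatty acids, glycolysis, mitochondrially encoded and nuclear oxidative phosphorylation genes, ribosomal proteins, ribosome biogenesis, oxidative stress, heat shock, interferon, inflammation, MHC class I, extracellular matrix and markers of glial, neuronal, leukocyte, endothelial and epithelial cells. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists within each of 3 comparisons, and again with a correlation estimated from the data. The named genes are the panel, and the 10 higher and 10 lower genes with the largest called change in each treatment contrast (6 in each direction for the other contrasts). The latter had a mean of at least 5 CPM and no overlap between groups where the contrast has a pair of groups. Named list members are those with the smallest p, to which the largest called changes against the direction of the list were added.

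A gene at 0 in a whole group is given a bound against a floor of 3 reads over the group, and a gene with 1 to 3 reads a ratio with its 95% counting interval. The share of mitochondrially encoded mRNA was compared by an exact two-sided permutation test, which cannot go below 0.1 with 3 against 3 samples. Replicate pairs differed by 2.29 to 3.86 times the chi-square per gene that read sampling alone gives. The labels name no batches, and groups of 3 are too small for the test of single deviating samples.

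The test was checked on simulated data of the same depths with added changes (dispersion 0.000966, seed 1). At folds of 1.2, 1.5, 2 and 4 it recovered 50%, 82%, 88% and 100% of changed genes in U87, 60%, 82%, 94% and 96% in U373, and 22%, 82%, 86% and 96% for the difference. Of the simulated calls 12.3% in U87, 9.5% in U373, 6.7% for the difference and 6.1% at baseline were false, above the nominal 5%. In U87, 26 of 13353 unchanged genes were called, and 18 of these 26 were low in some group. Only 50 genes were changed at each fold, besides a list of 30. The false shares therefore do not carry over to the real data, where 69.3% (U87) and 71.4% (U373) of genes were called. A list of 30 genes raised 1.5-fold was called in all 3 comparisons and 0 of 20 unchanged lists were. The simulated genes varied independently, whereas real lists were correlated, with an estimate of 0.669 for cytosolic ribosomal proteins. False list calls that come from correlation could therefore not appear in the simulation.

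Alternatives tried were other scalings, filters and pseudocounts, voom, a fit for each line alone, a replicate block, stricter fold thresholds, fry, the estimated correlation, mitochondrial genes left out before scaling, and each library left out in turn. Results for some single genes are not reported here. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.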

Results

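Total RNA of the human glioblastoma cell lines U87 and U373 was sequenced, with a library selection method that the labels do not state. Each line was given phosphate-buffered saline (PBS) or 1 U/ml of BCT-100, a pegylated form of arginase I, the enzyme that splits arginine into ornithine and urea. RNA was taken after 72 h. Each of the 4 groups held 3 libraries, numbered 1 to 3. The deposited table lists 1 value per gene and library, and its column totals ran from 22101094 to 23433112. In M reads, the depths recovered from the values ran from 18.89 (U373 PBS replicate 2) to 25.92 (U87 BCT-100 replicate 2). Between 14462 and 14790 genes had a value above 0 in a library, and 13628 genes were tested. Levels below are means of the deposited scaled read counts ± SD over n = 3 libraries, and fold changes are BCT-100 over PBS on the log2 scale with the standard error (SE) of the fit. Gene positions are those of the GRCh38 annotation. The p-values measure only the spread between these libraries, which may be technical, since the labels do not say whether the replicates were separate cultures.

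The first component of a principal component analysis held 82.68% of the variance and separated the lines, and the next held 10.02% and separated BCT-100 from PBS in each line. Mitochondrially encoded mRNA, a measure that also moves with RNA quality and cell state, made up 5.92% ± 0.124 of the U87 PBS libraries and 3.66% ± 0.056 of the U87 BCT-100 libraries. In U373 the shares were 4.31% ± 0.048 and 3.38% ± 0.071. An exact two-sided permutation test gave p = 0.1 in each line, the smallest value that 3 against 3 libraries allow. Genes whose symbols start with RPL or RPS and a digit took 3.73% ± 0.098 and 4.12% ± 0.106 in U87 (PBS and BCT-100). In U373 they took 3.38% ± 0.039 and 4.35% ± 0.096. They were picked by symbol alone, so the set is not the tested list of cytosolic ribosomal proteins and can hold other genes.

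The question of the first comparison was what 72 h of BCT-100 changed in U87. ASNS, asparagine synthetase (chromosome 7, 97852118 to 97872542), rose from 1665 ± 60.6 to 18228 ± 228, a log2 change of 3.45 (SE 0.04). ATF4, the transcription factor of the integrated stress response, rose from 3980 ± 18.2 to 13882 ± 398, or by 1.80 (SE 0.04). Its target CHAC1, a glutathione-degrading enzyme, rose by 3.54 (SE 0.08), and TRIB3, a pseudokinase induced by amino acid shortage, by 3.11 (SE 0.05). All 25 measured members of the ATF4 and integrated stress response list were higher, with a median of 2.05 (camera adjusted p = 1.2e-15, and adjusted p = 0.00867 with an estimated correlation). VEGFA, the angiogenic growth factor, rose by 2.03 (SE 0.04), and STC2, a secreted glycoprotein, rose by 2.78 (SE 0.04). The other stress genes of the panel rose as well, DDIT3 by 2.30 (SE 0.07) and SESN2, an inhibitor of mTORC1 signalling, by 2.60 (SE 0.05).

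Genes of amino acid synthesis and transport also rose in U87. Of 19 measured genes of amino acid and one-carbon synthesis, 15 were higher, 3 lower and 1 not called, with a median of 1.30 (camera adjusted p = 6.36e-06, but adjusted p = 0.111 with an estimated correlation). PSAT1 and PHGDH of serine synthesis rose by 2.83 and 2.14, and MTHFD2 of mitochondrial folate metabolism by 2.18 (SE 0.03 each), whereas cytosolic SHMT1 fell by 1.19 (SE 0.05). Amino acid transporters were higher in 13 of 18, with 3 lower and 2 not called (median 1.07, camera adjusted p = 0.000307, adjusted p = 0.149 with an estimated correlation). Their examples were SLC7A5 and SLC3A2, the chains of the large neutral amino acid transporter, at 2.73 and 2.49 (SE 0.03 each). The cationic amino acid transporter SLC7A1, which imports arginine, rose from 4840.3 ± 95.8 to 6857 ± 171, or by 0.50 (SE 0.03), and the cystine transporter SLC7A11 by 1.87 (SE 0.08). Among 20 cytosolic aminoacyl-tRNA synthetases, 14 were higher, 4 lower and 2 not called (median 0.96, camera adjusted p = 0.000275, adjusted p = 0.225 with an estimated correlation). YARS, for tyrosine, rose by 1.46 (SE 0.03) and QARS, for glutamine, fell by 1.63 (SE 0.05).

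Genes of arginine metabolism did not move together in U87. ASS1, argininosuccinate synthase, the first enzyme that remakes arginine from citrulline (chromosome 9, 130444929 to 130501274), rose from 2026 ± 58.9 to 4509.5 ± 104, or by 1.15 (SE 0.06). ASL, the enzyme of the next step, fell by 0.40 (SE 0.06), from 616 ± 28.8 to 468 ± 29.2. ARG2, the mitochondrial arginase, fell by 0.81 (SE 0.13), and ODC1, which makes putrescine from ornithine, by 0.37 (SE 0.03). The urea cycle gene OTC was listed at 0 in every library, and ARG1 had a mean of at most 0.646 in any group, so neither was tested. The list for arginine, urea cycle and nitric oxide had 5 genes higher, 7 lower and 4 not called (median −0.23, camera adjusted p = 0.507). The polyamine list had 4 higher, 4 lower and 8 not called (median −0.01, camera adjusted p = 0.954), with SAT1, the polyamine acetyltransferase, at 2.12 (SE 0.05).

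Proliferation genes fell in U87. MKI67, the marker of cycling cells (chromosome 10, 128096659 to 128126385), fell from 18639 ± 203 to 1645 ± 68.7, a log2 change of −3.50 (SE 0.03). All 36 mitosis genes were lower, with a median of −2.60 (camera adjusted p = 4.65e-23, and adjusted p = 0.00867 with an estimated correlation). Examples were the mitotic kinase PLK1 at −4.49 (SE 0.06), cyclin B1 (CCNB1) at −3.20 (SE 0.04) and topoisomerase TOP2A at −2.92 (SE 0.03). Of 40 DNA replication genes, 37 were lower and 3 not called, with a median of −0.97 (camera adjusted p = 1.5e-12, but adjusted p = 0.111 with an estimated correlation). RRM2, a ribonucleotide reductase subunit, fell by 2.35 (SE 0.05), while the helicase subunit MCM2 fell by 0.25 (SE 0.04). CDKN1A, the p21 inhibitor of cyclin-dependent kinases, rose by 0.69 (SE 0.06). Among p53 targets, 17 of 27 were higher, 6 lower and 4 not called (median 0.46, camera adjusted p = 0.0158, adjusted p = 0.198 with an estimated correlation). In that list GADD45A and the death receptor TNFRSF10B rose by 1.94 (SE 0.08) and 1.63 (SE 0.03), and TP53I3 was at −1.10 (SE 0.13). The BCL2 family and death receptor list had 16 of 24 higher, 3 lower and 5 not called (median 0.52, camera adjusted p = 0.00198, adjusted p = 0.111 with an estimated correlation). In it BIRC3, an inhibitor of apoptosis, was at 4.18 (SE 0.08) and PMAIP1, a promoter of it, at 2.40 (SE 0.05). The histone list had 4 of 11 higher, 2 lower and 5 not called (camera adjusted p = 0.535).

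Inflammatory genes rose in U87. IL6, the cytokine interleukin 6 (chromosome 7, 22725884 to 22732002), rose from 216 ± 4.51 to 20424 ± 695, or by 6.56 (SE 0.14). Of 27 measured inflammatory cytokines and NF-kB targets, 26 were higher and 1 not called, with a median of 2.72 (camera adjusted p = 8.44e-14, and adjusted p = 0.00867 with an estimated correlation). The chemokine CXCL2 rose by 5.11 (SE 0.09), NFKBIZ, a regulator of NF-kB, by 3.37 (SE 0.07), and SOD2, mitochondrial superoxide dismutase, by 2.80 (SE 0.04). Genes of MHC class I and antigen presentation were higher in 11 of 17, with 4 lower and 2 not called (median 0.52, camera adjusted p = 0.00987, adjusted p = 0.179 with an estimated correlation). HLA-B was at 1.44 (SE 0.03) and HLA-E at 1.14 (SE 0.03), with reads that HLA genes can share. The interferon list had 9 of 28 higher, 5 lower and 14 not called (median 0.10, camera adjusted p = 0.54). The leukocyte and microglial markers that could be tested had 0 higher, 2 lower and 1 not called (camera adjusted p = 0.337), and the summed level of all 13 went from 6314 to 2566, nearly all of it the lysosomal protein CD68. Epithelial markers summed to 130 and 315, with 2 of 6 higher, 1 lower and 3 not called (camera adjusted p = 0.601), and of the 5 endothelial and erythroid markers 2 were lower and 3 not called (camera adjusted p = 0.283).

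Oxidative stress genes were higher in 19 of 25 in U87, with 4 lower and 2 not called (median 0.56, camera adjusted p = 2.24e-05, adjusted p = 0.169 with an estimated correlation). Heme oxygenase HMOX1 rose by 2.01 (SE 0.04) and the ferritin chains FTH1 and FTL by 1.57 and 1.25 (SE 0.03 each). Glycolysis and hypoxia genes had 18 of 31 higher, 8 lower and 5 not called (median 0.35, camera adjusted p = 0.0243, adjusted p = 0.424 with an estimated correlation). The members that rose included the glucose transporter SLC2A1 at 1.63 (SE 0.05) and the mitophagy receptor BNIP3 at 1.58 (SE 0.04), while pyruvate kinase PKM fell by 0.75 (SE 0.02). Heat shock genes had 10 of 15 higher, 1 lower and 4 not called (median 0.28, camera adjusted p = 0.00987, adjusted p = 0.149 with an estimated correlation), with the chaperone HSPA8 at 0.50 (SE 0.03). All 13 mitochondrially encoded mRNAs were lower (median −0.72, camera adjusted p = 9.89e-07, adjusted p = 0.179 with an estimated correlation), such as MT-CO2 of complex IV at −0.89 (SE 0.02). Their nuclear-encoded partners of oxidative phosphorylation were lower in 31 of 40, with 5 higher and 4 not called (median −0.30, camera adjusted p = 2.87e-05, adjusted p = 0.223 with an estimated correlation). ATP5A1, a subunit of ATP synthase, fell by 1.49 (SE 0.03). Cholesterol synthesis had 18 of 24 lower, 0 higher and 6 not called (median −0.48, camera adjusted p = 0.000275, adjusted p = 0.149 with an estimated correlation). Glial and neural stem cell genes had 11 of 17 lower, 2 higher and 4 not called (median −0.52, camera adjusted p = 0.0365, adjusted p = 0.15 with an estimated correlation), such as nestin (NES) at −1.11 (SE 0.04). Without U87 BCT-100 replicate 1 that glial call was lost (adjusted p = 0.055), and without U87 PBS replicate 2 or 3 the median was −0.78 (adjusted p = 0.0246 and 0.0329).

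The other lists did not pass the test in U87. Ribosome biogenesis and MYC targets had 19 of 34 higher, 11 lower and 4 not called (median 0.19, camera adjusted p = 0.0776), and passed with a replicate block (adjusted p = 0.0499). Cytosolic ribosomal proteins had 29 of 49 higher, 15 lower and 5 not called (median 0.14, camera adjusted p = 0.0961), and passed without U87 PBS replicate 2 (adjusted p = 0.0426). ER chaperones had 13 of 27 higher, 12 lower and 2 not called (camera adjusted p = 0.346), with HSPA5 (BiP) at 1.47 (SE 0.03) and PDIA4 at −0.88 (SE 0.03). Autophagy and lysosome genes had 10 of 28 higher, 12 lower and 6 not called (camera adjusted p = 0.829), with the autophagy receptor SQSTM1 at 1.82 (SE 0.03). Fatty acid synthesis had 6 of 17 higher, 9 lower and 2 not called (camera adjusted p = 0.303), and extracellular matrix 10 of 34 higher, 16 lower and 8 not called (camera adjusted p = 0.0961), with vimentin (VIM) at −1.34 (SE 0.02). Neuronal genes had 3 of 11 higher, 4 lower and 4 not called (camera adjusted p = 0.657).

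Across all genes, 9450 of the 13628 tested genes were called in U87, 4584 higher and 4866 lower. Changes of at least 2-fold were seen in 1113 of the higher and 1227 of the lower genes. The largest rises by rule included SPRR2D, a cornified envelope protein of epithelium, from 21.1 ± 7.58 to 2773.5 ± 36.9, although its reads can fit related genes. The cytokine IL32 rose from 4.84 ± 1.44 to 549 ± 33.0, OLAH, a thioesterase, from 3.23 ± 0.961 to 529 ± 29.3, OSCAR, an immunoglobulin-like receptor, from 3.20 ± 1.23 to 461 ± 15.4, and the tight junction gene CLDN1 from 9.88 ± 2.32 to 947 ± 17.7. RGS16, a regulator of G protein signalling, had 0 reads in the 3 PBS libraries and a mean of 153 ± 22.1 with BCT-100, at least 155-fold higher. TNFSF8, the ligand of CD30, was likewise at least 125-fold higher, against a floor of 3 reads over the group. SPRR2A and the siderophore-binding LCN2 had 3 reads each in PBS, and their ratios were 187 (95% interval 63.6 to 909) and 146 (49.7 to 712). Such floors and intervals cover counting error only. By rule, with at least 5 CPM in PBS, the largest falls were in KIF20A, a mitotic kinesin, from 1898.5 ± 46.9 to 52.4 ± 8.32, in PLK1, PCDHGC5, PADI3, MPP4, SHROOM2, RAB7B, METTL7B, MKI67 and ASPM, between −3.50 and −5.16. PCDHGC5 lies in a cluster of protocadherin genes that share exons, so its reads are uncertain.

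The adjusted p-values came from limma with a trended prior, and 3 lists adjusted for an estimated correlation kept their call in U87, the stress response, mitosis and inflammatory lists. Adjusted over the list alone, the counts in U87 were the same as those above except for the transporters (4 lower), DNA replication (1 higher) and interferon (8 higher and 4 lower).

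In U373 the question was the same. ASS1 rose from 25.4 ± 1.26 to 666 ± 31.9. In the fit, made on the value plus 1, the change was 25.3-fold (log2 change 4.66, SE 0.06). STC2 (chromosome 5, 173314713 to 173329503) rose from 216 ± 15.7 to 18129 ± 776, or by 6.39 (SE 0.04), CHAC1 by 5.47 (SE 0.08) and ASNS from 754 ± 35.9 to 15439 ± 610, or by 4.35 (SE 0.04). Of the 25 genes of the ATF4 and integrated stress response list, 21 were higher, 3 lower and 1 not called, with a median of 2.95 (camera adjusted p = 2.04e-10, and adjusted p = 0.0372 with an estimated correlation). ATF4 itself rose by 2.25 (SE 0.04), SESN2 by 3.67 (SE 0.05), TRIB3 by 3.71 (SE 0.05), DDIT3 by 2.14 (SE 0.07) and VEGFA from 1993 ± 41.0 to 19643 ± 783, or by 3.30 (SE 0.04). ATF5, a related transcription factor, fell by 0.75 (SE 0.07).

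Of 19 genes for amino acid and one-carbon synthesis in U373, 14 were higher, 3 lower and 2 not called (median 1.80, camera adjusted p = 1.2e-05, adjusted p = 0.137 with an estimated correlation). PSAT1 rose by 3.77, MTHFD2 by 3.15 and PHGDH by 1.98 (SE 0.03 each), and SHMT1 fell by 1.63 (SE 0.05). Amino acid transporters had 13 of 18 higher, 3 lower and 2 not called (median 1.75, camera adjusted p = 3.72e-05, adjusted p = 0.137 with an estimated correlation). SLC7A1 rose from 2519 ± 9.84 to 12588 ± 468, or by 2.32 (SE 0.03), the glutamine transporter SLC38A1 by 3.18 (SE 0.03) and SLC7A11 by 1.90 (SE 0.08), and the taurine transporter SLC6A6 fell by 1.92 (SE 0.04). For the aminoacyl-tRNA synthetases 17 of 20 were higher and 3 lower (median 1.43, camera adjusted p = 6.92e-07, adjusted p = 0.177 with an estimated correlation), with YARS at 2.64 (SE 0.03) and QARS at −1.79 (SE 0.05). In the polyamine list 10 of 16 were higher, 3 lower and 3 not called (median 0.34, camera adjusted p = 0.0313, adjusted p = 0.41 with an estimated correlation). Its members ODC1, at 0.86 (SE 0.03), and SAT1, at 1.49 (SE 0.05), make and acetylate polyamines. The arginine list had 7 of 16 higher, 7 lower and 2 not called (median 0.14, or −0.16 with its member at 0 set to its bound, camera adjusted p = 0.947). In it ARG2 rose from 105 ± 13.3 to 203 ± 25.6, or by 0.95 (SE 0.13), and ASL fell from 877 ± 32.2 to 519 ± 18.9, or by 0.76 (SE 0.06).

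Proliferation genes fell in U373 too. MKI67 went from 29947 ± 1212 to 4832 ± 112, a log2 change of −2.63 (SE 0.03). Mitosis genes were lower in 34 of 36, with 1 higher and 1 not called (median −1.30, camera adjusted p = 2.1e-14, and adjusted p = 0.0372 with an estimated correlation). TOP2A was at −2.23 (SE 0.03) and CCNB1 at −2.02 (SE 0.04), against the spindle checkpoint gene MAD2L1 at 0.19 (SE 0.06). DNA replication genes were lower in 37 of 40 and higher in 3 (median −0.77, camera adjusted p = 1.63e-10, adjusted p = 0.137 with an estimated correlation). Thymidylate synthase TYMS fell by 1.47 (SE 0.03), the transcription factor E2F1 by 1.88 (SE 0.05) and MCM2 by 0.61 (SE 0.04), and ORC6 rose by 0.75 (SE 0.05). CDKN1A fell by 0.58 (SE 0.06). The p53 list had 10 of 27 higher, 13 lower and 4 not called (median −0.06, camera adjusted p = 0.947). Its members GADD45A and TNFRSF10B rose in U373 as they did in U87. Per library, GADD45A ran from 452 to 559 in PBS and from 2804 to 3404 with BCT-100. TNFRSF10B ran from 1362 to 1459 and from 4340 to 4461. The BCL2 list had 12 of 24 higher, 5 lower and 7 not called (camera adjusted p = 0.198). The histone list had 2 of 11 higher, 4 lower and 5 not called (camera adjusted p = 0.947).

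Ribosome biogenesis genes and MYC targets rose in U373, with 32 of 34 higher and 2 not called (median 1.01, camera adjusted p = 9.31e-13, adjusted p = 0.137 with an estimated correlation). MYC, the growth-promoting transcription factor, rose from 719 to 7302, or by 3.35 (SE 0.05), the nucleolar protein NOP58 by 1.99 (SE 0.04) and WDR43, of the small subunit processome, by 1.71 (SE 0.04). Cytosolic ribosomal proteins had 30 of 49 higher, 11 lower and 8 not called (median 0.31, camera adjusted p = 0.00175, adjusted p = 0.842 with an estimated correlation), from RPL27 at 1.11 (SE 0.03) to RPL4 at −0.72 (SE 0.03). All 24 cholesterol synthesis genes were lower (median −1.07, camera adjusted p = 1.47e-09, and adjusted p = 0.0372 with an estimated correlation). INSIG1, a sterol sensor, fell by 2.12 (SE 0.05). Mitochondrially encoded mRNAs had 12 of 13 lower and 1 higher (median −0.34, camera adjusted p = 0.00175, adjusted p = 0.458 with an estimated correlation), with MT-CO3 at −0.69 (SE 0.02) and MT-ND1 at 0.22 (SE 0.02). Their nuclear-encoded partners were lower in 27 of 40, with 6 higher and 7 not called (median −0.19, camera adjusted p = 0.00314, adjusted p = 0.464 with an estimated correlation).

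Inflammatory genes were higher in 16 of 27 in U373, with 1 lower and 10 not called (median 0.29, camera adjusted p = 0.0047, adjusted p = 0.223 with an estimated correlation). The cytokine IL11 rose by 2.83 (SE 0.07) and CXCL2 by 2.23 (SE 0.09), and the chemokine CCL2 fell by 2.65 (SE 0.20). Interferon response genes had 14 of 28 lower, 1 higher and 13 not called (median −1.13, camera adjusted p = 0.0298, adjusted p = 0.858 with an estimated correlation), with STAT2, a transcription factor of the interferon response, at −1.06 (SE 0.08). That call was lost without U373 PBS replicate 1 (median −0.46, adjusted p = 0.0546). Neither line's list of ER chaperones passed, and in U373 it had 11 of 27 higher, 13 lower and 3 not called (camera adjusted p = 0.947). Autophagy had 14 of 28 higher, 12 lower and 2 not called (camera adjusted p = 0.983), oxidative stress 13 of 25 higher, 10 lower and 2 not called (camera adjusted p = 0.225), and heat shock 7 of 15 higher, 5 lower and 3 not called (camera adjusted p = 0.715). HMOX1 was at 3.97 (SE 0.04) among the oxidative stress genes. Glycolysis had 14 of 31 higher, 15 lower and 2 not called (camera adjusted p = 0.986), fatty acid synthesis 5 of 17 higher, 8 lower and 4 not called (camera adjusted p = 0.715), and MHC class I 7 of 17 higher, 6 lower and 4 not called (camera adjusted p = 0.947). Extracellular matrix had 12 of 34 higher, 15 lower and 7 not called (camera adjusted p = 0.687), glial genes 4 of 17 higher, 10 lower and 3 not called (median −0.97, camera adjusted p = 0.0885), and neuronal genes 2 of 11 higher, 8 lower and 1 not called (camera adjusted p = 0.108). The neuronal list passed without U373 BCT-100 replicate 2 (adjusted p = 0.0456). Leukocyte markers had 1 of 3 higher, 1 lower and 1 not called (camera adjusted p = 0.715), with a sum over 13 markers of 475 and 230, endothelial markers 3 of 5 lower and 2 not called (camera adjusted p = 0.585), and epithelial markers 1 of 6 higher, 1 lower and 4 not called (camera adjusted p = 0.947).

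In U373, 9724 genes were called, 4849 higher and 4875 lower, and 1135 of the higher and 1382 of the lower genes changed at least 2-fold. Cyclin D2 (CCND2, chromosome 12, 4273772 to 4305350) had 0 reads in PBS and a mean of 260 ± 23.7 with BCT-100, at least 264-fold higher. The other large rises by rule were PTCHD1 (5.14, SE 0.43), BEX2 (4.92, SE 0.15), the netrin receptor UNC5B (4.79, SE 0.06), CTH, cystathionine gamma-lyase (4.47, SE 0.11), and HOXB9 (4.35, SE 0.19). By the same rule the largest falls were in PI15, a secreted protease inhibitor, from 4116.5 ± 141 to 171 ± 11.5, in PRSS35 from 5194 ± 213 to 223 ± 46.9, and in GALNT5 from 867 ± 54.8 to 36.5 ± 4.16. CAPS (row 2), 1 of the entries that share a symbol, KRT13, SLC38A11, RCAN2, KRT15, KIF20A and HRCT1 followed, between −3.67 and −4.51. With an estimated correlation 3 lists kept their call in U373, the stress response, mitosis and cholesterol lists. Adjusted over the list alone, the counts in U373 were the same except for ribosomal proteins (31 higher), ribosome biogenesis (1 lower), interferon (0 higher and 13 lower) and neuronal genes (9 lower).

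**Figure D1:**
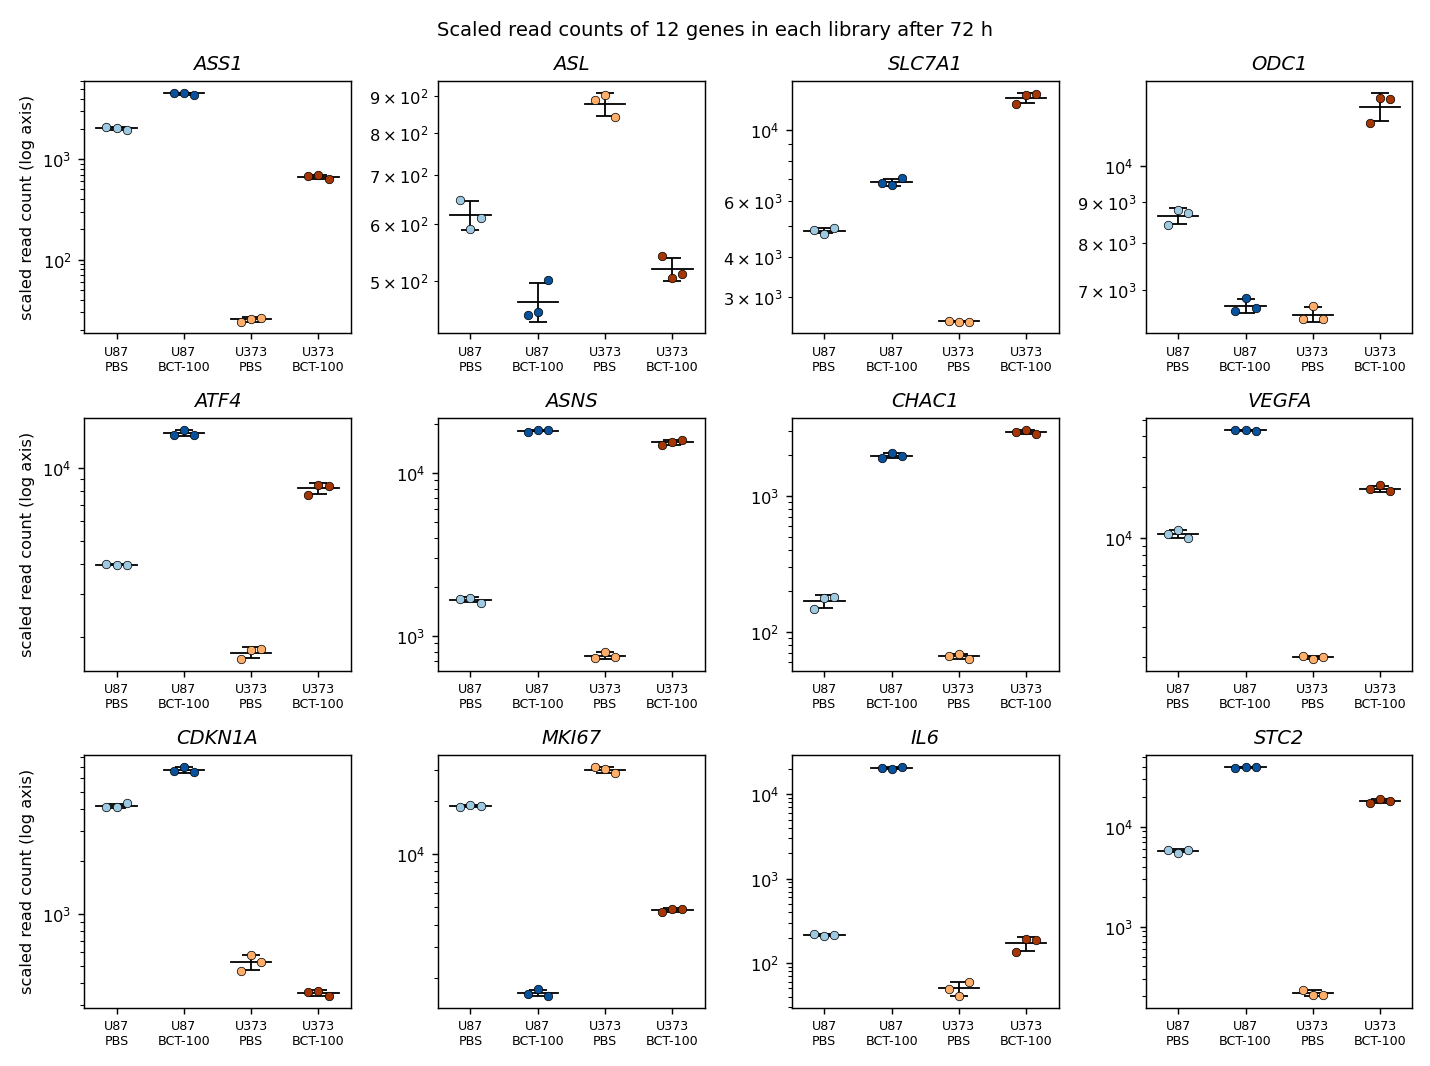
Scaled read counts (log axis) of 12 genes in each of the 12 libraries, with the points as libraries, the long bar as the group mean and the whiskers as 1 SD (n = 3). ASS1 stood at 25.4 in untreated and 666 in treated U373, and MKI67 was lower with BCT-100 in both lines.

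**Figure D2:**
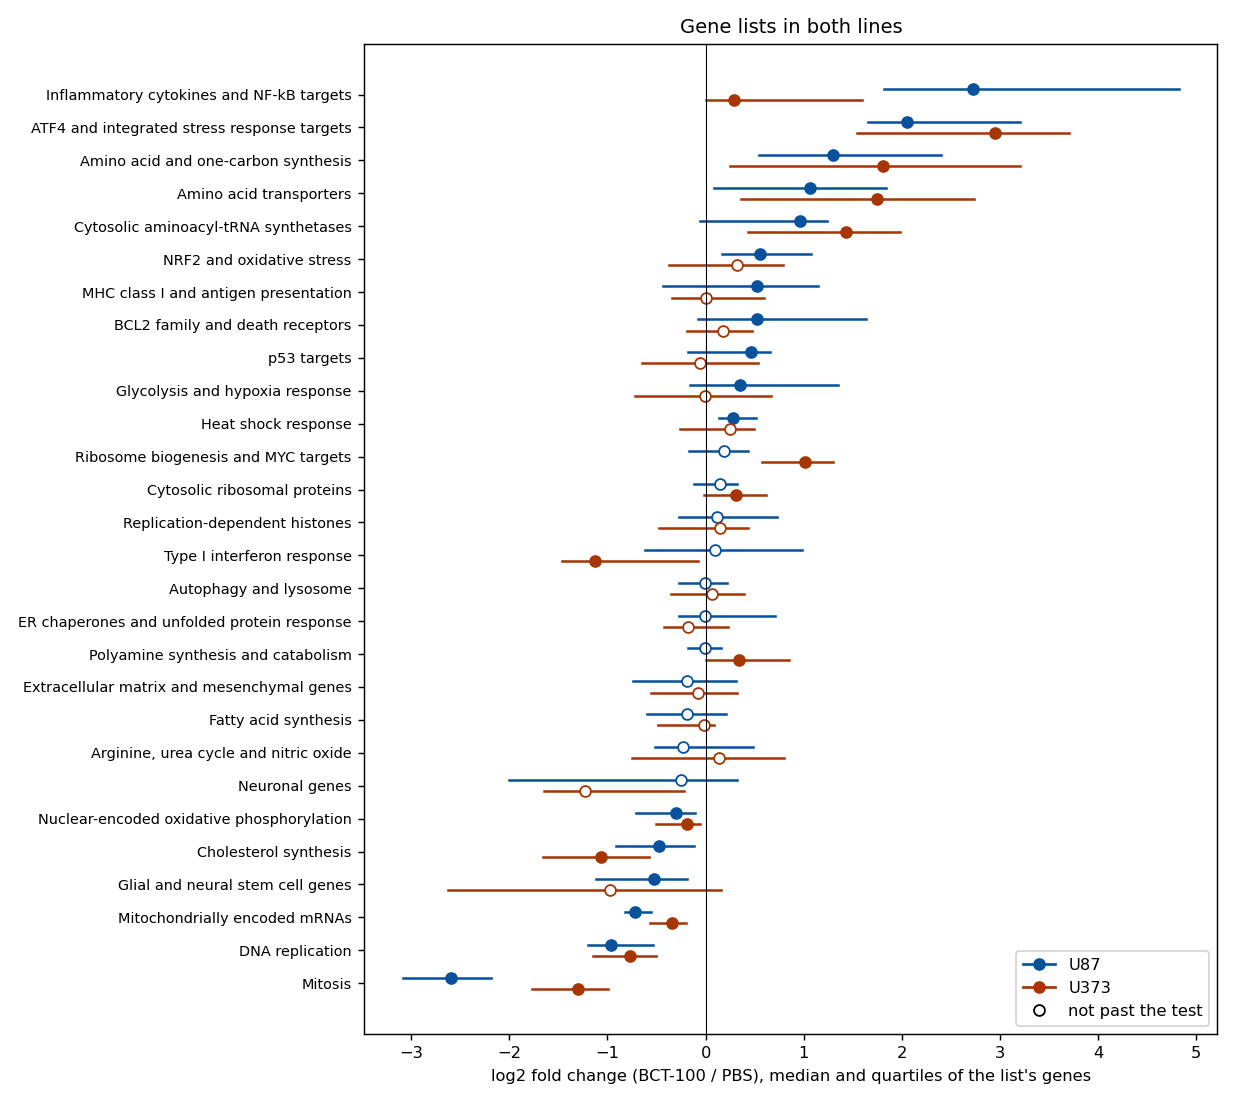
Median log2 fold change (point) and quartiles (line) of each list with at least 10 measured genes, in U87 (blue) and U373 (orange), with open points where the camera test did not pass. The inflammatory list had a median of 2.72 in U87 and 0.29 in U373.

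A further comparison asked whether the lines responded alike. Across the 13628 genes the log2 fold changes of U87 and U373 had Pearson's r = 0.496 and Spearman's rho = 0.535, values that describe genes, which are not independent replicates. In both lines 3033 genes were higher, where independent calls would give 1631, and 3144 were lower, against 1741. Opposite calls were made for 1299 genes, against 3371, and 71 of these changed at least 2-fold each way, 38 of them higher in U87. At 2-fold or more, 426 genes were higher in both lines and 535 lower in both, against 93 and 124. KIF20A fell by 5.16 in U87 and 3.76 in U373, UNC5B rose by 3.88 and 4.79, and PHGDH by 2.14 and 1.98. The correlation depended on how genes with low values were treated, from 0.436 with no filter to 0.605 with a separate fit for each line.

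**Figure D3:**
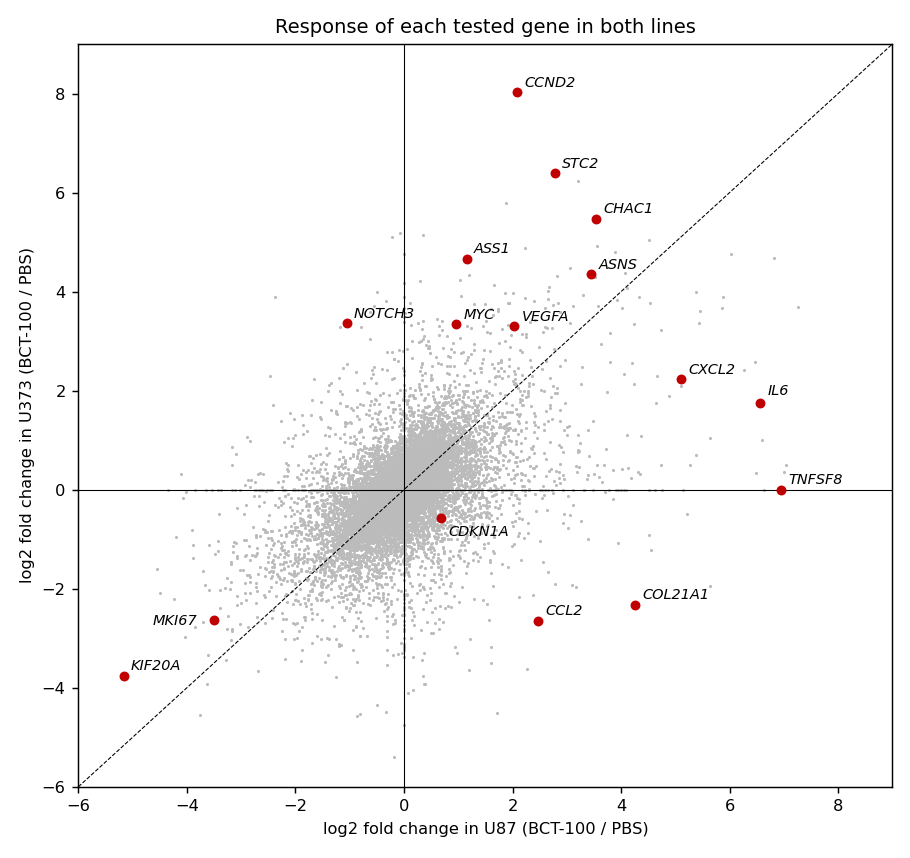
Log2 fold change of each of the 13628 tested genes in U87 (x axis) and U373 (y axis), with equal changes on the dashed line. STC2 and ASS1 lie above the line, IL6 lies below it, and the places of genes at 0 in a group, such as CCND2 and TNFSF8, depend on the pseudocount.

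The difference of the responses was then tested gene by gene, and 7740 genes differed, 3552 with the larger value in U87 and 4188 with the larger value in U373. The ASS1 change was smaller in U87 by 3.51 on the log2 scale (SE 0.08, adjusted p = 3.38e-17). Its untreated level was higher in U87, by 76.9-fold in the fit on the value plus 1. CDKN1A rose in U87 and fell in U373 (difference 1.26, SE 0.08), while ODC1 and ARG2 fell in U87 and rose in U373 (differences −1.23, SE 0.04, and −1.75, SE 0.18). COL21A1, a collagen chain, rose by 4.25 in U87 and fell by 2.32 in U373 (SE 0.16 each). NOTCH3, a cell surface receptor, fell by 1.06 in U87 and rose by 3.36 in U373 (SE 0.23 each), and the sialyltransferase ST6GALNAC3 was at −1.18 and 3.29 (SE 0.31 each). TRABD2A and CRMP1 rose in U373, by 4.21 and 3.70, and were at 0.30 and −0.54 in U87, where neither passed the test. For SLC7A11 and DDIT3 no difference was called (−0.04, SE 0.12, adjusted p = 0.824, and 0.16, SE 0.09, adjusted p = 0.165), although DDIT3 passed without U373 BCT-100 replicate 2 (0.24, adjusted p = 0.0281).

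Of the lists, 15 differed between the lines. Mitosis genes fell further in U87, with 35 of 36 below U373 and 1 not called (median −1.26, camera adjusted p = 9.69e-19, and adjusted p = 0.0181 with an estimated correlation). Inflammatory genes rose further in U87, with 24 of 27 above, 1 below and 2 not called (median 2.24, camera adjusted p = 3.72e-13, and adjusted p = 0.0181 with an estimated correlation). The lower quartile of that list in U373 was 0. A gene at 0 in U373, as CSF3 was, has a change of 0 there, so its difference is its U87 rise alone. All 34 ribosome biogenesis genes were below U373 (median −0.86, camera adjusted p = 8.36e-17, adjusted p = 0.137 with an estimated correlation), with MYC at −2.38 (SE 0.07). Cholesterol synthesis had 18 of 24 above, 3 below and 3 not called (median 0.52, camera adjusted p = 2.14e-05, adjusted p = 0.137 with an estimated correlation), INSIG1 differing by 2.18 (SE 0.07). The tRNA synthetases had 17 of 20 below, 1 above and 2 not called (median −0.43, camera adjusted p = 5.46e-06, adjusted p = 0.268 with an estimated correlation). Amino acid synthesis had 11 of 19 below, 3 above and 5 not called (median −0.58, camera adjusted p = 0.00914, adjusted p = 0.417 with an estimated correlation), and transporters 9 of 18 below, 2 above and 7 not called (median −0.23, camera adjusted p = 0.0257, adjusted p = 0.417 with an estimated correlation).

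Interferon genes had 12 of 28 above U373, 1 below and 15 not called (median 0.81, camera adjusted p = 0.00176, adjusted p = 0.566 with an estimated correlation), with IFI35 at 2.80 (SE 0.25). Without U373 PBS replicate 1 that median was 0.52 (adjusted p = 0.00148). MHC class I had 11 of 17 above, 4 below and 2 not called (median 0.62, camera adjusted p = 0.00527, adjusted p = 0.268 with an estimated correlation). Its member CD74 was at 0 in every U373 library, so the difference for CD74 is its U87 change alone. Glycolysis had 18 of 31 above, 8 below and 5 not called (median 0.28, camera adjusted p = 0.00527, adjusted p = 0.417 with an estimated correlation), SLC2A1 differing by 2.51 (SE 0.07). Oxidative stress had 13 of 25 above, 4 below and 8 not called (median 0.17, or 0.26 without U373 PBS replicate 2, camera adjusted p = 0.00914, adjusted p = 0.417 with an estimated correlation). Mitochondrially encoded mRNAs were below in 11 of 13, with 2 not called (median −0.37, camera adjusted p = 0.000924, adjusted p = 0.417 with an estimated correlation), and ribosomal proteins in 29 of 49, with 3 above and 17 not called (median −0.21, camera adjusted p = 0.000924, adjusted p = 0.6 with an estimated correlation). The p53 list had 12 of 27 above, 6 below and 9 not called (median 0.32, camera adjusted p = 0.0378, adjusted p = 0.417 with an estimated correlation), and the BCL2 list 11 of 24 above, 3 below and 10 not called (median 0.25, camera adjusted p = 0.0333, adjusted p = 0.268 with an estimated correlation). The p53 call was lost without U87 PBS replicate 1, U87 BCT-100 replicate 3 or U373 BCT-100 replicate 1 (adjusted p = 0.065, 0.0512 and 0.0549), and the BCL2 call without U87 BCT-100 replicate 2 (adjusted p = 0.0562).

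No difference was called for the stress response list, with 7 of 25 above, 15 below and 3 not called (median −0.45, camera adjusted p = 0.0906), nor for DNA replication, with 13 of 40 above, 14 below and 13 not called (camera adjusted p = 0.848). The arginine list had 3 of 16 above and 6 below (camera adjusted p = 0.425), polyamines 4 of 16 and 8 (0.207), autophagy 10 of 28 and 9 (0.224), histones 3 of 11 and 0 (0.425), fatty acid synthesis 4 of 17 and 7 (0.576) and oxidative phosphorylation 6 of 40 and 19 (0.113). Heat shock had 8 of 15 above and 4 below (camera adjusted p = 0.14), extracellular matrix 10 of 34 and 15 (0.548), glial genes 9 of 17 and 4 (0.425), neuronal genes 5 of 11 and 2 (0.521), leukocyte markers 1 of 3 and 0 (0.99), endothelial markers 1 of 5 and 1 (0.99) and epithelial markers 1 of 6 and 1 (0.733). ER chaperones, with 12 of 27 above and 5 below, were near the threshold (median 0.12, camera adjusted p = 0.0557) and passed with median-ratio scaling (adjusted p = 0.0352), with TMM scaling (0.04), and without U87 BCT-100 replicate 1 (0.0407), U373 PBS replicate 1 (0.0453) or U373 BCT-100 replicate 2 (0.0345). Adjusted over the list alone, the counts of the difference were the same except for tRNA synthetases (2 above), autophagy (11 above), histones (1 above), BCL2 genes (12 above), oxidative phosphorylation (7 above and 20 below), interferon (11 above) and leukocyte markers (1 below). Median, mean and test differed in sign only for lists that were not called, namely polyamines, autophagy, histones and ER chaperones in U87, the arginine list, autophagy, histones, glycolysis, leukocyte and epithelial markers in U373 (where MHC class I had a median of 0), and leukocyte and endothelial markers in the difference.

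The untreated lines were compared as the background of both responses. GFAP, the intermediate filament of astrocytes (chromosome 17, 44903161 to 44916937), stood at 3.58 ± 0.364 in U87 and 52216 ± 1592 in U373, and CRYAB, a small heat shock protein, at 9.90 ± 5.67 and 39873 ± 2733. U87 carried TFPI2, a protease inhibitor, at 36511 ± 1437, against 3.40 ± 2.16 in U373. GREM1, an antagonist of BMP signalling, was at 12469 ± 234 in U87 with 0 reads in U373, at least 12600-fold higher, and TMPRSS15, XYLT1 and SERPINB2 were at least 6770-fold, 4780-fold and 4620-fold higher. EREG, a ligand of the EGF receptor, had 3 reads in U373 and a ratio of 8590 (95% interval 2940 to 41700). GFRA1 and EPB41L3 were at least 9530-fold and 6320-fold higher in U373, where THY1 and PXDN had ratios of 16400 (4540 to 135000) and 14700 (4060 to 121000) over the 2 reads of each in U87. Of the 13628 genes, 11325 differed, 5864 higher in U87 and 5461 higher in U373, and 4833 by at least 2-fold. Inflammatory genes were higher in untreated U87 in 23 of 27 and in U373 in 3, with IL1B, an example chosen after its values were seen, at 5894 ± 739 in U87 and 10.8 ± 0.883 in U373. In turn 12 of 17 glial genes were higher in U373 and 5 in U87. Of 27 p53 targets, 22 were higher in U87 and 0 in U373. Those counts describe the lines and were not tested as lists.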

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

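The tests of U87 RNA in treated U373, of leukocytes in treated U87 and of library scaling were chosen only after the results they bear on were seen. The response to BCT-100 differed between the lines for 7740 genes. In 100 splits of the libraries within the lines, 1, the real one, gave as many, and the median of the others was 0. The other splits mix treated and untreated libraries in at least 1 line, which puts the treatment effect itself into the spread. They therefore cannot decide whether chance made the responses differ. The highest other split gave 4902 and kept the real groups of a single line, a structure of the samples that calls many genes by itself. For U87 the real split gave 9450 genes and the highest other 2, for U373 9724 and 1, and for the untreated lines 11325 and 0. In each of these only 1 of 10 splits, the real one, was as large, and 10 splits are too few for a share under 0.05.

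In the fit on the value plus 1, ASS1 rose 25.3-fold in U373 and 2.23-fold in U87, a log2 difference of −3.51. If U87 RNA or cells in the treated U373 libraries were the source, 14.2% of the U87 level would be needed, but the median share over 45 genes at 500 or more in U87 and at most 1 in untreated U373 was 0 (quartiles 0 to 0.0376, with 25 at 0 and 0 reaching the share). Reads shared with other annotated copies of ASS1 would leave fractional counts, and the recovered count was whole within 0.02 in 12 libraries. Of these, 11 were whole to rounding and U373 BCT-100 replicate 1, at 640.98, lay at the edge of the allowance and was counted as inside it after it had been seen. Copies that are not annotated were not tested, so a response of ASS1 to BCT-100 that depends on the line may be the source and remains a hypothesis.

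Inflammatory genes rose further in U87 (median difference 2.24), where any gene at 0 in U373 counts by its U87 rise alone. Leukocytes in the treated U87 libraries would bring their own transcripts, but 11 markers under 100 in untreated U87 summed to 9.09 before and 17.2 after treatment, 0.0068% of the inflammatory rise of 253600. An earlier form of that test with all 13 markers met neither of its bounds, because U87 itself carries CD68 and CSF1R, whose fall gave a change of −1.48% of the rise, and it was replaced after that was seen. The GC content and transcript length trend explained 0.533% of the spread over all genes and ran from −0.11 at percentile 1 to 0.19 at percentile 99, too small for such a median, which was 2.31 without it. A difference between the lines in the induction of these genes may account for it, as a hypothesis.

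Ribosome biogenesis genes rose further in U373 (median difference −0.86). The same small GC content and transcript length trend is below that size too, and the median was −0.92 without it. The scaling of the libraries moves every gene of a library alike. Relative to the median of all genes (−0.04) the list stood at −0.83 (quartiles −0.97 to −0.62). Because that median was already small in the deposited values, subtracting it could change little. The result therefore gives the place of the list among all genes and does not decide whether scaling shifted all genes together. An earlier scaling test was dropped, because its alternative factors were too close to 1 to change the outcome. A line-specific response may account for it, as a hypothesis, and with an estimated correlation the list no longer passed (adjusted p = 0.137).

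The other lists that differed, by a test of the difference itself and with U87 minus U373 as the sign, had medians of −0.58 (amino acid synthesis), −0.23 (transporters), −0.43 (tRNA synthetases), −1.26 (mitosis), 0.32 (p53), 0.25 (BCL2), 0.52 (cholesterol), 0.28 (glycolysis), −0.37 (mitochondrially encoded mRNAs), −0.21 (ribosomal proteins), 0.17 (oxidative stress), 0.81 (interferon) and 0.62 (MHC class I). The p53 call was lost without U87 PBS replicate 1 (median 0.36), U87 BCT-100 replicate 3 (0.29) or U373 BCT-100 replicate 1 (0.33), and the BCL2 call without U87 BCT-100 replicate 2 (0.25). The interferon median was 0.52 without U373 PBS replicate 1, a library in which IFIT1 and IFI35 stood above the other untreated U373 libraries. The oxidative stress median was 0.26 without U373 PBS replicate 2.

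Of 58 tested genes of the panel and of the largest changes by rule in the treatment contrasts and in the difference, list members and baseline genes left aside, 55 differed between the lines. Those taken for the difference were chosen because it was called. Those taken for a treatment contrast were chosen for a large change in a single line, which itself favours a difference. Of all 13628 tested genes 56.8% differed, so the higher share among the named genes partly reflects how they were selected. The 34 given here moved in opposite directions (6) or differed by over 2 on the log2 scale (31), 21 differed by less and 3 did not pass. Values for genes at 0 or with few reads in a group depend on the pseudocount. Among the 34, OSCAR, with 3 reads in untreated U373, lost its call with a pseudocount of 0.25 (1.46) and with voom (1.75), with adjusted p from 2.15e-07 to 0.147 over its settings. SHROOM2, with 9 and 3 reads in untreated and treated U373, lost its call with a pseudocount of 0.25 (−2.17), with adjusted p from 5.14e-06 to 0.0838. Differences were −1.75 for ARG2, −1.23 for ODC1, 1.26 for CDKN1A, 3.57 for RGS16, 6.53 for SPRR2D, 6.65 for OLAH, 6.95 for TNFSF8, 2.15 for OSCAR, 6.63 for SPRR2A, 5.58 for IL32, 4.80 for IL6, 6.15 for LCN2 and 3.90 for CLDN1. PLK1 differed by −2.39, PCDHGC5 by −2.02, PADI3 by −3.25, MPP4 by −3.91, SHROOM2 by −2.76, CCND2 by −5.94, STC2 by −3.60 and PTCHD1 by −4.79. PI15 differed by 3.71, GALNT5 by 3.73, CAPS (row 2) by 6.22, KRT13 by 4.16, SLC38A11 by 3.84, RCAN2 by 4.17, KRT15 by 2.55 and COL21A1 by 6.57. ST6GALNAC3 differed by −4.47, NOTCH3 by −4.41, CRMP1 by −4.25 and TRABD2A by −3.92.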

How the results depend on the processing

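The trimmed-mean scaling (TMM) was the normalisation of the first design, but it was added as an alternative setting only after the data were seen. The pseudocounts 0.25 and 4 were also added then, and the other settings before. Among those, voom used recovered counts, which could be derived only from the deposited values. The counts of called genes stayed within 1.5 times their values except under fold thresholds. A fold of at least 2 left 2340 (U87), 2517 (U373), 1903 (difference) and 4833 (baseline), and limma's treat against 1.5-fold 2768, 3179, 1747 and 5846. Across libraries left out in turn the counts ran from 8944 to 9454, 9268 to 9714, 7337 to 7566 and 10968 to 11319. The correlation of the responses was 0.436 with no filter, 0.524 at 1 CPM, 0.481 with voom, 0.605 with each line fitted alone, 0.463 and 0.522 with pseudocounts 0.25 and 4, and 0.514 over genes called in either line. With an estimated correlation 3, 3 and 2 lists passed, and with fry, which asks a different question, 29, 27 and 28. Among lists that either test called, the sign under fry was reversed against camera for the arginine (0.135), p53 (−0.062) and ER chaperone (−0.182) lists in U373 and the glial difference (1.02), and the cause was not tested. Of 15273 settings of named genes 15077 were unchanged, 100 lost and 96 gained a call, and 0 reversed. The replicate numbers do not pair the samples (correlations −0.07 to 0.023), and with a replicate block 9408, 9671, 7650 and 11339 genes were called. The share of higher calls in U87 was 48.5%, 44.3% with total scaling and 41.6% with total scaling without mitochondrial genes. The DESeq2 alternative was not run. Depth limits the genes at 0 to 3 reads in a group.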

Other observations

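The test of arginine content was planned, and the genes and regions given as further biology were chosen only after their values were seen. Runs were sought among genes at 100 or more in either untreated line, so genes below that level can lie between their members. In U87 a run of 5 such genes on chromosome 9 (20341665 to 22455740), MLLT3, FOCAD, KLHL9, MTAP and DMRTA1, was at 0 in both groups. Untreated U373 carried MTAP, of methionine salvage, at 2273 ± 93.1 and FOCAD at 1589 ± 74.3. The nearby HAUS6 and RPS6 stood at 1531 ± 60.3 and 11261 ± 610 in untreated U87. CDKN2A and CDKN2B, which inhibit cell cycle kinases and lie in the same region, were at 0 in both lines. In U87 a run of 8 zinc finger genes on chromosome 19 (36604817 to 37130314) was also below 1 in both groups. Other runs were found in both lines, such as 5 MHC class II genes on chromosome 6 in U373. CD74, the invariant chain of MHC class II, went the same way as these class II genes. It was at 4386 ± 191 in untreated U87 and 0 in U373, at least 4450-fold higher in U87. The class II activator CIITA was at 1463 ± 47.6 and 0.917 ± 0.921. Some other class II genes were low rather than at 0 in untreated U373, such as HLA-DMA at 11.2, against 458.5 in untreated U87. MHC class II was not tested as a list.

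LDHA, lactate dehydrogenase A, was higher in untreated U87 than in U373 by 5.93 on the log2 scale, and BCT-100 changed it by 0.35 in U87 and −0.83 in U373 (SE 0.03 each). CSF3, a granulocyte growth factor, rose from 3454 ± 534 to 21719 ± 1169 in U87 and was at 0 in U373. In the matrix list, SPARC fell by 2.08 and 1.83 and COL1A2 by 1.52 and 1.86 in U87 and U373 (SE 0.03 each). The glial genes GFAP and PDGFRA fell by 2.39 (SE 0.16) and 2.64 (SE 0.12) in U373. Among autophagy genes MAP1LC3B rose by 1.63 and 1.15 (SE 0.03 each), and HSPA5 among ER chaperones by 1.47 and 1.35 (SE 0.03 each).

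A shortage of arginine might change transcripts by the arginine content of the encoded protein. Over 13001 genes Spearman's rho of that share with the fold change was −0.031 in U87 and −0.05 in U373. Arginine ranked 4 and 5 by size among the 20 amino acids, behind leucine in U87 (−0.052) and lysine in U373 (0.089), which met neither bound set in advance. Leucine had the larger correlation in both lines (−0.052 and −0.085). The planned test therefore could not decide whether arginine content shaped the response. The arginine share tracked little of the ranking of fold changes across these genes (−0.031 in U87 and −0.05 in U373).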
